A study of Hypsibius dujardini with 126 samples.

How the data were processed

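RNA was measured in 126 single embryos of the tardigrade Hypsibius dujardini by CEL-Seq, a method that tags the 3' end of polyadenylated RNA with a barcode per sample and amplifies it by transcription in vitro. Per the labels' protocols, each embryo was isolated, watched until the 2-cell stage, kept at 20 °C for its number of hours and frozen before extraction. The time tag in the labels counts minutes after fertilization, whereas the growth protocol counts hours past the 2-cell stage. Label times are used here in hours as given, so time zero is uncertain. Nothing in the labels ties embryos to a mother or clutch, so p-values measure the spread between embryos, some of which may be siblings.

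The deposited values were raw read counts per transcript model, not normalized. Per the submitters' processing notes, CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3 were used. The genome build and the transcript annotation are not given in the sources used here. The deposited counts hold 12746 transcript models, each treated as a gene, 92 ERCC spike-in RNAs and 5 summary rows of the counting program. Spike-ins and summary rows were kept out of library sizes and tests. Reads outside any transcript model took a median of 6.64% of all counted and uncounted reads per embryo, and reads that did not align took a median of 47.8%. No molecular identifiers are part of the counts, so reads are not independent molecules, and intervals and floors cover counting error only. The files do not pair the transcript IDs with gene names, and no reference was used, so the 15 gene lists fixed beforehand were not applied.

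The embryos were grouped by label time into 10 windows of 10 h each. The embryo at the 1-cell stage and the 2-cell embryos belong to the first window. Embryo numbers in the labels run through the course in 3 stretches: embryos 1-25 cover 0 to 18 h and 80 to 98 h, embryos 26-78 cover 47 to 99 h, and embryos 79-126 cover the 1-cell stage to 46 h. These stretches are called runs of embryo numbers. The labels name no batches. The runs were defined from embryo numbers and label times, and spike-in ratios differ between them.

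Total transcript counts ranged from 2347 to 4972036 per embryo, with a median of 634045. Embryos under 10% of that median were left out, which kept 101 embryos and removed 25. A gene with 100 counts has a counting error of 10.0%, and the spread between embryos was larger than this.

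Differential expression was tested with edgeR 4.0.16 (R 4.3.3), with TMM normalization, the package's default filter on low counts, trended dispersions and the quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method and compared with 0.05. One fit over all 10 windows gave the 9 contrasts of consecutive windows and the contrast of the first and last windows. A natural cubic spline of time with 5 degrees of freedom tested for change along the course, with 2-cell embryos at 0 h and the 1-cell embryo left out. Genes found to change were assigned to the window with their highest mean log2 CPM (counts scaled to a common library size, prior count of 2). Age was estimated for each embryo as the mean label time of the 3 other embryos with the highest Spearman correlation across genes. For detected genes, embryos with at least 20% of the median total were thinned without replacement to 129668 counts. Group differences in single measures were tested by permutation, exact or with 100000 resamples, all 2-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.

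The rule for named IDs was fixed before the data were examined, as were the design and the first group of alternatives below. It took the 2 IDs with the largest rise and the 2 with the largest fall between the first and last windows, among genes past the threshold with a mean of at least 50 CPM in the higher window and the same direction within embryos 1-25 and within embryos 26-126. Alternatives fixed then were RLE factors, DESeq2 1.42.0, no filter on low counts, other depth filters, a term for the run, single runs, a test against a 1.5-fold change, other spline degrees of freedom, and leaving out each of the 4 kept embryos of the 60-69 h window. Alternatives chosen after seeing the data were limma 3.58.1 on log2 CPM, leaving out embryos with over 10% of counts on a single transcript, counting only genes seen in 50% or more of the embryos of the higher window, leaving out each of the 4 last-window embryos within embryos 1-25, shuffles of age labels within runs, and further splits by run.

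The tests were tried on simulated counts with 200 of 11802 genes changed. A first simulation with 2-fold and 4-fold changes, drawn at the trended dispersion of these embryos (median 1.66), recovered few of them. Larger changes, a gene-wise dispersion (median 1.77) and a low dispersion of 0.1 were then added to separate an error in the code from a lack of power. At the low dispersion, 98.0% of 4-fold changes between the first and last windows were recovered. At the trended dispersion, recovery for that contrast was 4.0% at 2-fold, 10.0% at 4-fold, 72.0% at 8-fold and 86.0% at 16-fold. For 60-69 h against 70-79 h it was 4.0% at 16-fold, and 22.0% with gene-wise dispersions. With gene-wise dispersions, 38 of 124 genes called between the first and last windows were unchanged ones, as were 128 of 208 called by the spline, so the counts of genes below include false calls of very variable genes beyond the nominal rate. The ranking of same-hour embryos was tested by replacing 1 embryo of each pair with a thinned copy of its partner, and it placed the copy first in 15 of 15 pairs. Such a copy carries no noise of a second preparation and no difference between runs. The test therefore does not show that RNA prepared again would be found.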

Results

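The series followed gene expression through the embryonic development of Hypsibius dujardini at nearly hourly resolution, from the 1-cell stage to 99 h, in 126 single embryos. The 10 windows of label time held 19, 18, 10, 10, 10, 10, 10, 10, 15 and 14 embryos, of which 17, 13, 7, 9, 10, 10, 4, 9, 8 and 14 passed the depth filter. Median total counts per window ranged from 29207 at 60-69 h to 1126738 at 0-9 h. Embryos 79-126 had a median of 156 transcript counts per spike-in count, against 7.91 in embryos 1-25 and 5.03 in embryos 26-78. The run of embryo numbers changed from 79-126 to 26-78 between 46 and 47 h, so age and run cannot be separated across that hour. Embryos 1-25 cover both ends of the course but not the hours around that change.

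**Figure D1:**
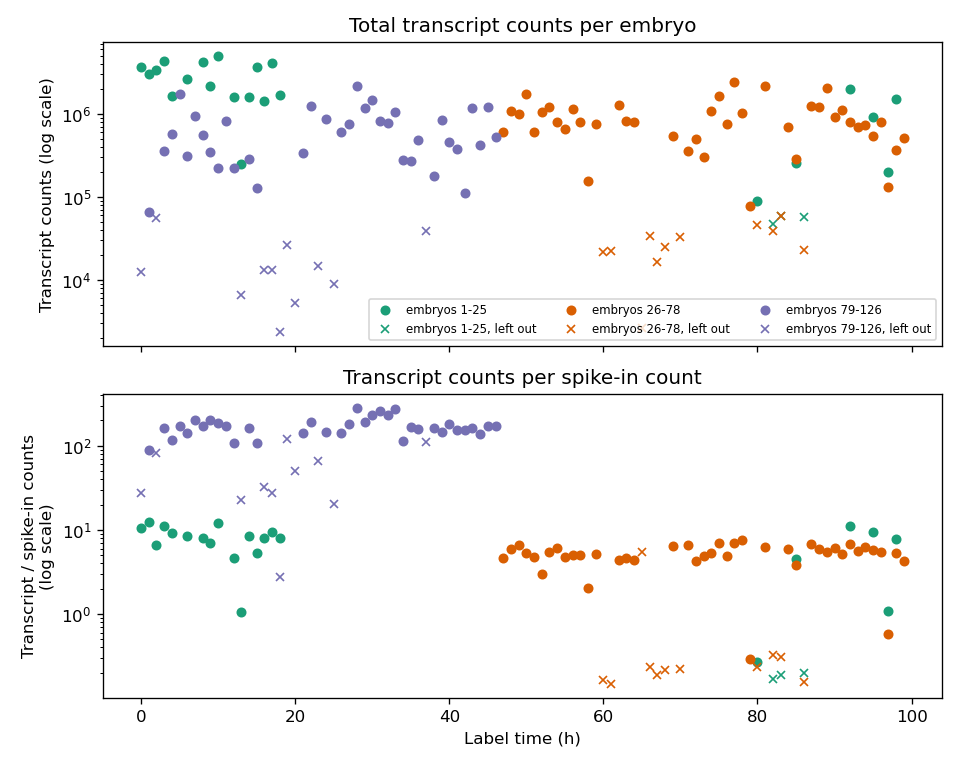
Total transcript counts per embryo (upper panel) and transcript counts per spike-in count (lower panel), both on log axes, against label time in hours. Points are single embryos coloured by run of embryo numbers, and crosses are the 25 embryos left out for low depth; embryos 79-126 lie around 156 transcript counts per spike-in count and the other runs around 7.91 and 5.03.

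Most tested genes changed with label time over the whole course. The run of embryo numbers changes along that course, so the calls can include differences between runs. Of 11798 genes tested, 10209 changed along the course in edgeR's quasi-likelihood test of the time spline. Genes with their highest expression in the first window formed the largest group, with 2093 of the 10208 changing genes that were also in the window table. A further 1380 peaked at 20-29 h, 974 at 60-69 h, 1046 at 80-89 h and 1283 at 90-99 h. The other windows held 946 (10-19 h), 663 (30-39 h), 682 (40-49 h), 660 (50-59 h) and 481 (70-79 h). The first window stayed the largest group in each alternative, but group sizes moved. RLE factors put 3276 genes at 0-9 h. Embryos 26-126 alone put 1781 at 0-9 h, nearly the same number, 1768, at 80-89 h, and 839 at 90-99 h. Within single runs, 4582 of 7396 genes changed in embryos 79-126 and 3541 of 10680 in embryos 26-78, with a spline of 3 degrees of freedom, and 7908 changed along the whole course with a term for the run.

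**Figure D2:**
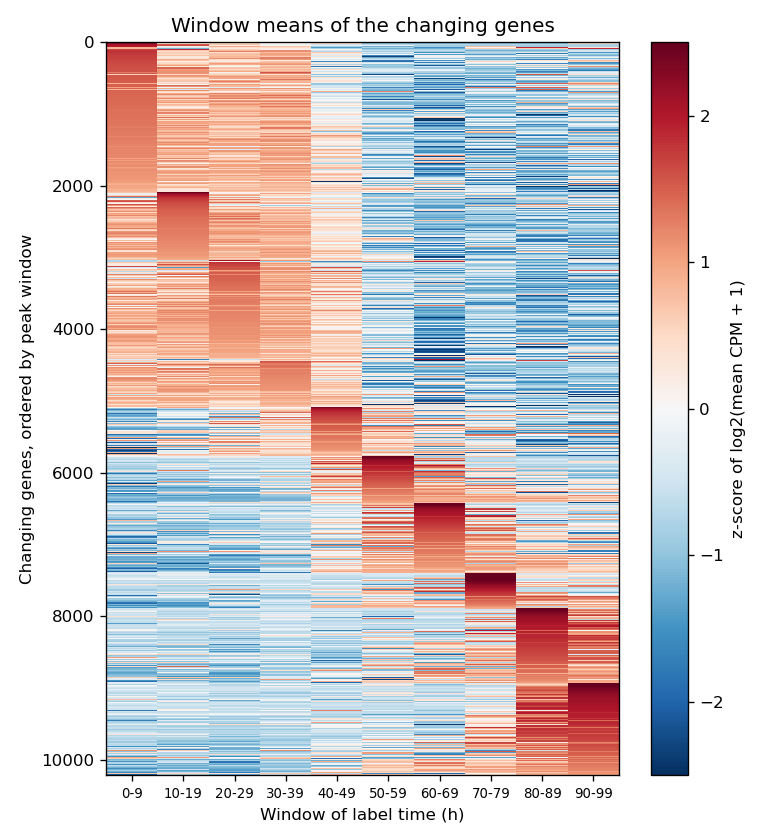
Window means of the 10208 changing genes as z-scores of log2(mean CPM + 1), with genes as rows ordered by peak window and windows of label time in hours as columns. Red marks windows above a gene's own mean and blue windows below it; 2093 genes peak in the first window and 1283 in the last.

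Among changing genes, 1415 had a mean under 1 CPM in the first window and reached a mean of 50 CPM later. Of these, 38 first reached that level at 20-29 h, 11 at 30-39 h, 160 at 40-49 h, 288 at 50-59 h, 228 at 60-69 h, 247 at 70-79 h and 343 at 80-89 h. The embryos from 47 to 79 h all belong to embryos 26-78, which are absent from the first window, and 4 embryos were kept at 60-69 h, so these times carry the change of run. Of 714 genes with at least 50 CPM at the start that had a later mean under 1 CPM, 219 first did so at 50-59 h and 374 at 60-69 h, under the same limits. Of the 714, 113 stayed under 1 CPM from then on and 210 were under it in the last window. In 1186 genes, 621 of them among the 1415, a mean between 20 and 79 h reached 50 CPM and was over 4-fold above both end windows. Of these, 253 had their highest mean at 50-59 h, 319 at 60-69 h and 271 at 70-79 h. These are counts of window means without a test of each step.

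The contrast of the last window with the first asked how the embryo near the end of the course differs from the early embryo. Of 11802 genes, 7916 differed, 3647 higher and 4269 lower at 90-99 h. The split depended on scaling and on the model. RLE factors gave 2868 higher and 6644 lower, DESeq2 2205 and 6619, and limma on log2 CPM 2898 and 5630. The median log2 change of all genes was -0.56 with TMM and -1.96 with RLE. Higher genes were in the majority with a term for the run (3152 and 2779), with no embryo left out (3381 and 2873), with the stricter depth filter (3973 and 3337) and in embryos 26-126 (3238 and 3171). The contrast was repeated within embryos 1-25 and within embryos 26-126. In embryos 26-126 the first window held only embryos 79-126 (n = 9) and the last only embryos 26-78 (n = 10). Age and run therefore cannot be separated in that set, whereas embryos 1-25 are a single run. Of 10280 genes tested in both sets, 4694 differed within embryos 1-25 and 5909 within embryos 26-126. Of these, 3991 were shared and 3986 had the same direction, 2285 higher and 1701 lower, where independent lists would share 680 and 664. Across genes, which are not independent replicates, the log2 changes of both sets had a Pearson correlation of 0.853 and a Spearman correlation of 0.851.

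The largest falls were from transcripts present in every early embryo. HD_v1_tr_04349 had 420 ± 176 CPM (SD, n = 17) at 0-9 h, with counts in 17 of 17 embryos, and no count in any of the 14 embryos at 90-99 h. Pooled over the 17 embryos it had 410 CPM, at least 1544-fold above a floor of 3 counts over the later group (fitted log2 change -11.80, SE 1.28, edgeR adjusted p = 4.87e-13). HD_v1_tr_10738 went from 252 ± 102 CPM (SD, n = 17) to no count in 14 embryos, with 300 CPM in the pooled first window, at least 1129-fold above the same floor (edgeR adjusted p = 2.86e-12). Between these ends, HD_v1_tr_04349 was at 154 ± 178 CPM (SD, n = 9) at 30-39 h and 27.6 ± 53.9 CPM (SD, n = 10) at 40-49 h. HD_v1_tr_10738 was at 147 ± 142 CPM (SD, n = 9) and 11.1 ± 19.2 CPM (SD, n = 10) in those windows. The run of embryo numbers changed within the 40-49 h window, so age and run cannot be separated in the timing of these falls.

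The largest rises differed in their timing. HD_v1_tr_06466 had 1 count in the 17 embryos of the first window and 524 ± 382 CPM (SD, n = 14) in the last, where 12 of 14 embryos had counts. The ratio of pooled CPM was 17762, with an exact 95% Poisson interval of 3188 to 701574 (edgeR adjusted p = 7.18e-17). It stood at 31.7 ± 69.3 CPM (SD, n = 10) at 40-49 h and 354 ± 220 CPM (SD, n = 10) at 50-59 h. The run of embryo numbers changed within the first of these windows, so age and run cannot be separated in the timing of this rise. HD_v1_tr_00811 was at 0.605 ± 1.28 CPM (SD, n = 17) at the start and 2134 ± 889 CPM (SD, n = 14) in the last window, with counts in 14 of 14 embryos (log2 change 11.58, SE 0.82, edgeR adjusted p = 3.38e-22). It reached 26.7 ± 51.4 CPM (SD, n = 4) at 60-69 h, 405 ± 486 CPM (SD, n = 9) at 70-79 h and 2258 ± 655 CPM (SD, n = 8) at 80-89 h. The rule for naming IDs required the same direction within embryos 1-25 and within embryos 26-126, and the files do not pair them with gene names.

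**Figure D3:**
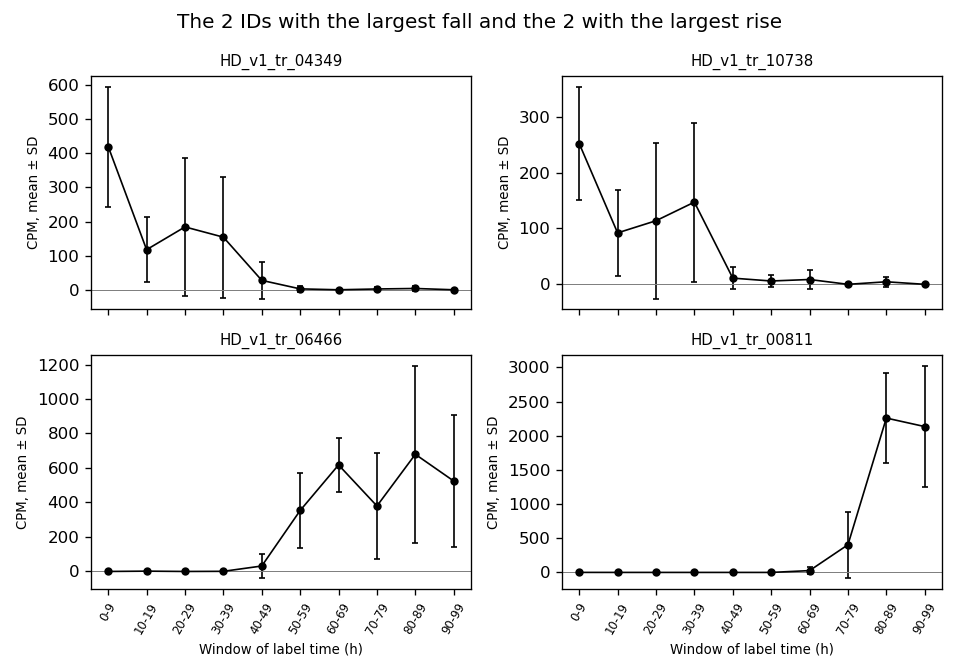
Mean CPM with SD bars in each window of label time (hours) for the 2 IDs with the largest fall (upper row) and the 2 with the largest rise (lower row) between the first and last windows. HD_v1_tr_00811 rises from 0.605 CPM to 2134 CPM and HD_v1_tr_04349 falls from 420 CPM to no counts.

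Contrasts of consecutive windows asked when expression changed most. Between 0-9 h and 10-19 h 816 genes differed, 598 higher and 218 lower in the later window. The next steps were small, with 154 genes between 10-19 h and 20-29 h and 12 between 20-29 h and 30-39 h. From there 1177 genes differed between 30-39 h and 40-49 h (740 higher, 437 lower) and 2504 between 40-49 h and 50-59 h (882 higher, 1622 lower). Later steps gave 1160, 1410, 2279 and 883 genes, and the step from 70-79 h to 80-89 h raised 1249 and lowered 1030. With RLE factors the first step gave 445 higher and 502 lower, and the step into 40-49 h gave 533 higher and 1439 lower. DESeq2 gave 380 higher and 640 lower at the first step, 457 and 2238 at the step into 40-49 h, and 672 and 946 at the step into 80-89 h, where the run term gave 1087 and 1144.

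The step at 40-49 h to 50-59 h coincided with the change of run, and with a term for the run it fell to 670 genes, 361 higher and 309 lower. That term also reduced the step before it to 336 genes (128 higher, 208 lower). The 40-49 h window kept 7 embryos of embryos 79-126 and 3 of embryos 26-78, and the 50-59 h window embryos 26-78 alone. That term would therefore also take up part of a developmental change between 46 and 47 h, so neither fall separates run from age. Within embryos 79-126, 593 genes differed between 30-39 h and 40-46 h, 216 higher and 377 lower, but between 33-39 h and 40-46 h edgeR called 0 (n = 6 and 7; 948 at an unadjusted p under 0.05). The first step had 885 genes with the run term, 35 within embryos 26-126 and 132 within embryos 1-25. From 60-69 h to 70-79 h, each of the 4 kept embryos of the earlier window decided the count, which lay between 757 and 890 without 1 of them. Counting only genes seen in 50% or more of the embryos of the higher window left 557 genes at that step, 610 at the step before it, 1142 at the step into 80-89 h and 197 at the last.

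**Figure D4:**
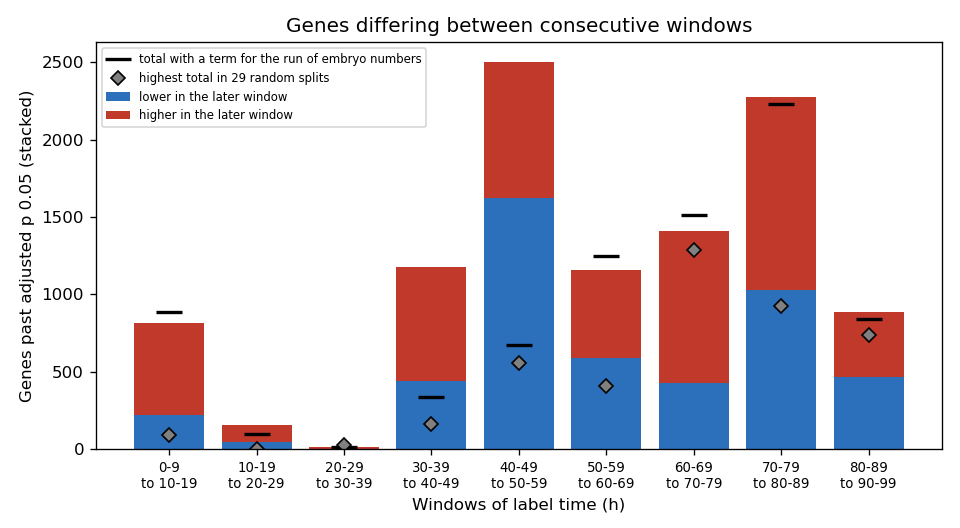
Number of genes past an adjusted p of 0.05 between consecutive windows of label time (hours), as stacked bars of genes lower (blue) and higher (red) in the later window. Black dashes give the total with a term for the run of embryo numbers and diamonds the highest total among 29 random splits. The tallest bar, 2504 genes, drops to 670 with the run term, which cannot separate run from age at that step.

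Detected genes and the share of the most abundant ones were compared between the first and last windows, which differ in run: the first holds embryos 1-25 and 79-126, the last embryos 1-25 and 26-78. At equal depth, 7267 ± 267 genes (SD, n = 16) were detected at 0-9 h and 5425 ± 1545 (SD, n = 14) at 90-99 h (permutation p = 4e-05), but the number also fell at the change of run, from 7668 ± 255 (SD, n = 6) at 40-46 h to 5872 ± 515 (SD, n = 7) at 47-53 h, so run and age cannot be separated in this difference. Within embryos 1-25 the values were 7184 ± 336 (SD, n = 8) and 5739 ± 1944 (SD, n = 4; exact permutation p = 0.0485). That difference of -1446 shrank to -510 without embryo 24 (exact permutation p = 0.145). With 3 late embryos left it was larger without embryo 23 (-1725, exact permutation p = 0.0848), embryo 25 (-1563, p = 0.145) or embryo 22 (-1985, p = 0.0121). Without embryos with over 10% of counts on a single transcript, the last window of the whole set had 5955 ± 769 genes (SD, n = 12; permutation p = 2e-05, the smallest the resampling can give). The 10 most abundant genes took 12.1% ± 2.99 of counts (SD, n = 17) in the first window and 19.1% ± 9.01 (SD, n = 14) in the last (permutation p = 0.00026). Without embryos with over 10% of counts on a single transcript, the last window had 16.2% ± 2.72 (SD, n = 12; permutation p = 0.00152). Within embryos 1-25 this difference did not pass the threshold (11.0% ± 3.00 against 17.5% ± 6.20, n = 8 and 4, exact permutation p = 0.0646), though it did without embryo 23 (20.1% ± 3.94, n = 3, p = 0.0242).

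The age read from an embryo's transcriptome was related to its label, with marked exceptions. The median absolute difference between label and estimate was 3.83 h (n = 100), against at least 20.3 h in 1000 shuffles of the labels over all embryos and at least 11.2 h in 1000 shuffles within runs. Estimated within single runs it was 1.83 h in embryos 1-25, 2.17 h in embryos 26-78 and 7.67 h in embryos 79-126, where 1000 shuffles within the run gave medians of 31.2, 15.5 and 13.2 h and lowest values of 4.17, 6.83 and 6.17 h (p = 0.00599 in embryos 79-126). In that last run the Spearman correlation of estimate and label was 0.678. The 7 kept embryos at 30 to 36 h were placed 8.33 to 16.0 h too early. So were embryo 120 (40 h) by 15.7 h, embryo 55 (76 h) by 32.0 h and embryo 17 (80 h) by 44.3 h. Embryo 17 had 51.3% of its 90771 counts on a single transcript. In the first window 15 of 16 embryos were placed too late, by a median difference of 9.5 h and up to 24.0 h. All kept embryos of the last window were placed too early, with differences of -1.0 to -10.3 h. An average over other embryos is drawn inwards at both ends of the course, so these directions are partly set by the method. Embryos 1-25 estimated from embryos 26-126 alone differed from their labels by a median of 8.33 h. The 16 of these from the first 18 h were all placed between 12.3 and 31.0 h, with a median difference of 10.0 h. The 6 from 80 h differed by a median of 4.5 h, with a maximum of 57.7 h in embryo 17.

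**Figure D5:**
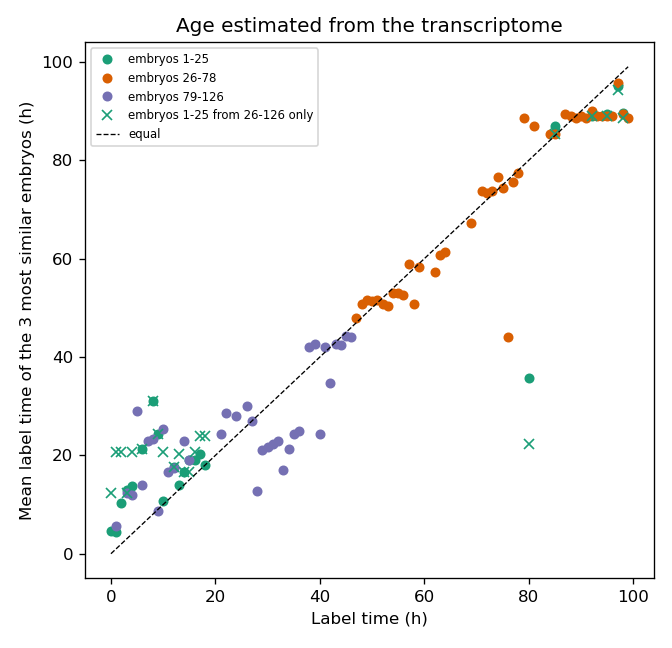
Mean label time of the 3 most similar embryos against label time, both in hours, 1 point per embryo coloured by run of embryo numbers, with crosses for embryos 1-25 estimated from embryos 26-126 alone. The dashed line marks equality; the median absolute difference is 3.83 h, and crosses from the first 18 h lie between 12.3 and 31.0 h.

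Embryos of the same hour in different runs were less alike than neighbours within a run. The mean Spearman correlation across genes was 0.739 in 14 same-hour pairs and 0.780 between the later-numbered embryo and its neighbours 1 h away, lower in 10 of 14 pairs (exact permutation p = 0.0115). The difference was -0.061 over 9 pairs of the first 18 h (exact permutation p = 0.00781) and -0.005 over 5 pairs from 80 h (exact permutation p = 1).

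Depth changed with age in 1 run. In embryos 1-25 log10 total counts fell with time (Pearson r = -0.70, permutation p = 0.00023, adjusted 0.00184; Spearman rho = -0.66, permutation p = 0.00055, adjusted 0.0044; n = 25), and r was -0.75 without the 2 embryos farthest from the median time. The relation did not pass the threshold in embryos 26-78 (r = 0.01, permutation p = 0.942, rho = -0.06, permutation p = 0.675, n = 53) or embryos 79-126 (r = 0.27, permutation p = 0.0665, rho = 0.27, permutation p = 0.065, n = 47). Without those 2 embryos r was 0.01 and 0.21. Transcript counts per spike-in count did not pass the threshold in any run. In embryos 1-25 their log10 values gave r = -0.37 (permutation p = 0.0682, n = 22). Without embryos with over 10% of counts on a single transcript, r was -0.12 (permutation p = 0.621, n = 19). Adjustment was over 8 relations with time.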

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

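Among 25 groups of 4 to 10 embryos checked for a value far from the others, 4 embryos stood apart, where chance gives about 1 in 20 groups. The tests of a single transcript against spike-ins in the embryos it dominates and against other transcripts at the same hours were chosen after the result was seen. Embryo 37 (58 h) had 2042 genes at equal depth, against 5180 to 6456 in the 9 others of its window. Embryo 108 (28 h) had 279 transcript counts per spike-in count, against 141 to 191 in the 6 others. The 10 most abundant genes took 54.0% of counts in embryo 58 (79 h), against 14.6% to 23.7% in the others, and 70.2% in embryo 17 (80 h), against 10.5% to 18.0%.

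HD_v1_tr_06538, named after its values were seen, held 33.2% of counts in embryo 58 and 51.3% in embryo 17. It was the most abundant transcript in 18 of the 20 embryos with over 10% of counts on 1 transcript, at 10.4% to 72.5%, and 15 of the 20 were already left out for depth. High expression in those embryos is argued against if the same amount of spike-in went into each: its median share was 56.6% in them and 1.8% in the 39 other embryos 1-78 of the same windows, but its median ratio to spike-in counts was 1.10 times as high. A background that follows the spike-ins is a candidate explanation: in embryos 1-78 the SD of log2(transcript / spike-in counts) was 0.258, against 2.53 relative to the other transcripts. RNA of the embryo recovered like its other transcripts is argued against, because in 10 same-hour pairs of the first 18 h it was 13.4 to 121 times as high relative to other transcripts in embryos 1-25 as in embryos 79-126 (median 50.9), and 1.51 to 6.62 times relative to spike-ins; in embryos 79-126 the SDs were 1.27 and 1.09, and whether the reads come from the spike-in mix or the reaction stays open.

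Reads outside the comparisons were frequent in a few libraries. Reads that did not align numbered 21791333 in embryo 31 (52 h) and 11602300 in embryo 58 (79 h), 92.9% and 96.8% of all reads. They numbered 146353 in embryo 93 (13 h), 198462 in embryo 96 (16 h) and 62881 in embryo 98 (18 h). These 5 embryos exceeded 90%, and the highest share elsewhere was 87.6%.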

How the results depend on the processing

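Of 277 alternative values, 219 were scored as unchanged, and the cause was not tested for the others unless given. The 219 include 13 for each of the 4 named IDs, which were picked for their large changes in these same data. Counts had to stay within 1.5 times, and tests had to keep their direction and side of the threshold. The median age error had to lie within 6.91 h (1 SD of the errors) of the main 3.83 h. All 8 alternatives of the age estimate met that wide bound. Limma, the filter on a single dominant transcript, the requirement of counts in 50% of embryos, leaving out single embryos of embryos 1-25, and most splits by run were chosen after seeing the data. Changing genes numbered 8516 to 11225 over the alternatives fixed beforehand, except 7908 with a term for the run; 4582 of 7396 genes changed in embryos 79-126 and 3541 of 10680 in embryos 26-78, over a shorter span with 3 degrees of freedom.

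For 0-9 h to 10-19 h, embryos 26-126 gave 35 genes, embryos 1-25 gave 132 (147 without dominated embryos), and genes seen in 50% of embryos 497. For 10-19 h to 20-29 h the counts were 96 with the run term, 14 in embryos 26-126 and 261 with DESeq2. For 20-29 h to 30-39 h they were 63 with no embryo left out, 28 in embryos 26-126, 22 with the run term and no dominated embryo, 75 with DESeq2 and 0 with limma (213 at an unadjusted p under 0.05; edgeR 12). For 30-39 h to 40-49 h they were 1972 with RLE, 2695 with DESeq2, 336 with the run term, 354 with that and no dominated embryo, and 593 within embryos 79-126. For 40-49 h to 50-59 h the run term gave 670, and 637 without dominated embryos. For 50-59 h to 60-69 h, leaving out 1 embryo of the later window gave 660 to 894, limma 628 and genes seen in 50% of embryos 610. For 60-69 h to 70-79 h these were 757 to 890, 695 and 557. For 70-79 h to 80-89 h genes seen in 50% of embryos numbered 1142. For the last step the counts were 523 with the stricter depth filter, 305 in embryos 1-25, 386 there without dominated embryos, 426 with limma and 197. Embryos 1-25 gave 5021 genes between the first and last windows.

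Peak counts moved with RLE to 3276 (0-9 h), 546 (10-19 h), 228 (30-39 h) and 305 (40-49 h). By the fitted spline they were 494 (10-19 h) and 144 (40-49 h). In embryos 26-126 they were 1768 (80-89 h) and 839 (90-99 h), and with the run term 424 (30-39 h) and 925 (70-79 h). The 4 named IDs stayed past the threshold in all 13 alternatives each, although the naming rule had fixed their direction in embryos 1-25 and in embryos 26-126. The same-hour difference was -0.00496 from 80 h (exact permutation p = 1), and the share of the 10 most abundant genes rose by 6.44 points in embryos 1-25 (exact permutation p = 0.0646), by 5.601, 4.22 and 6.84 there without embryos 22, 24 and 25 (p = 0.182, 0.194 and 0.097). Genes at equal depth changed there by -1446, and by -1725, -510 and -1563 without embryos 23, 24 and 25 (p = 0.0848, 0.145 and 0.145). The correlation of total counts with time was -0.05 over all embryos, -0.70 in embryos 1-25, 0.0103 in embryos 26-78 and 0.269 in embryos 79-126. Depth left 4 embryos at 60-69 h, and simulated 16-fold changes to 70-79 h were recovered in 4.0% of genes, or 22.0% with gene-wise dispersions.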

Other observations

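The tests of shared low yield by Fisher's exact test, of one library sequenced again, of 30-39 h against 40-46 h within embryos 79-126 and of genes seen in 50% of embryos were chosen after the result was seen. Random regroupings of the embryos, 30 with the real one, tested whether chance groupings give as many genes. Chance is argued against for change along the course, where 1 of the 30 orders, the real one, gave 10209 genes and the highest other 1634 (median 614). The same holds for 0-9 h against 90-99 h, with 7916 genes in the real split and 560 in the highest other. It also holds for the steps from 0-9 h (816, highest other 87), 10-19 h (154, highest other 0), 30-39 h (1177, highest other 160), 40-49 h (2504, highest other 557), 50-59 h (1160, highest other 408), 70-79 h (2279, highest other 926) and 80-89 h (883, highest other 740). The random splits regrouped several pairs of windows in 1 fit, which also changed the spread shared by all windows. Their counts may therefore be lower than with a single pair regrouped. The real split can rank no better than 1 in 30, without adjustment over the contrasts. The regroupings ignored the run, so a difference between runs is not excluded where windows differ in it: the step from 10-19 h gave 14 genes within embryos 26-126 and 96 with the run term, and the step from 30-39 h gave 336 with the run term. The step from 0-9 h gave 885 with that term, 132 within embryos 1-25 and 35 within embryos 26-126. Within embryos 79-126, 593 genes differed between 30-39 h and 40-46 h, but edgeR called 0 between 33-39 h and 40-46 h (948 at an unadjusted p under 0.05). Between 20-29 h and 30-39 h, 3 of the 30 splits gave 12 genes or more, up to 24, so chance cannot be excluded there. Between 60-69 h and 70-79 h the real split gave 1410 genes and the highest other 1288, but by genes seen in 50% of embryos 3 of 30 splits gave as many as the real 557, up to 745. Random splits of late embryos called many genes, with a median of 559 at the last step, which points to a structure of those samples in which genes with counts in few embryos pass the test.

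The largest step of the main fit, into 50-59 h, falls where the run of embryo numbers changes. It was not the largest in all settings. The step into 80-89 h gave more genes with the run term (2231 against 670) and with no embryo left out (2080 against 2000). With DESeq2 the step into 40-49 h did (2695 against 2099). Across the switch, 1114 genes differed between 40-46 h and 47-53 h, against 34 between 47-53 h and 54-60 h. Between 33-39 h and 40-46 h edgeR called 0 genes, with 948 at an unadjusted p under 0.05. A difference between runs may therefore account for much of the step into 50-59 h, and so may a lower recovery of transcripts in embryos 26-78. At equal depth 5872 ± 515 genes (SD, n = 7) were detected at 47-53 h and 7668 ± 255 (SD, n = 6) at 40-46 h (exact permutation p = 0.00117). A developmental change at that hour stays open, and no embryo of another run covers it.

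Of the 9 hours from 80 h with an embryo in both runs, 5 (80, 82, 83, 86 and 97 h) had under 1.5 transcript counts per spike-in count in embryos 17-25, and the same 5 did in embryos 26-78, while the 11 other late hours of embryos 26-78 had none (Fisher's exact test p = 0.00794, with cutoff and hours chosen from the values). Over all 25 shared hours, with the depth filter as cutoff, 3 had both embryos left out, 7 the embryo outside embryos 1-25 alone, 6 of these in the first 18 h, and 15 neither (p = 0.0522; p = 0.0476 over the 9 from 80 h), so chance agreement stays open. One library sequenced again is argued against, with a chi-square per degree of freedom of at least 4.27 between the counts of each of the 25 pairs, against at most 1.09 for a library split at random. The same RNA prepared more than once is a possible explanation: without the time trend, the same-hour embryo of the other run was the best match in 5 of 15 pairs, where chance gives 1.08, but of the 5 low hours 97 h alone was in this test, since the others lost an embryo to the depth filter. The count lies between the bounds set for and against it, so repeated RNA and separate embryos of that hour cannot be told apart; if it held, n would be overstated where runs overlap.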
